A study of Homo sapiens with 22 samples.

How the data were processed

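RNA of DU-145 and PC3 prostate cancer cells was measured on 22 two-colour Agilent arrays, 1 file per array, in 16 conditions. Per the file headers, the spot values are scanner intensity for Cy5 and Cy3 with local background, from Agilent Feature Extraction. The same files hold processed signals, an intensity after background subtraction with spatial detrending and dye normalization. The deposited value table holds log2 ratios of Cy5 over Cy3, and the authors state within-array loess. Loess of the median spot signals without background subtraction gave the same values (correlation 1), so the table is on a log2 scale with Cy5 over Cy3, and its column medians lay between 0.000577 and 0.00949. It correlated with the log ratios computed here between 0.9477 and 0.9959. The labels give a condition for each channel, and each condition is a single source name.

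Values were computed from the spot intensities in R 4.3.3 with limma 3.58.1 (statmod 1.5.0). Background was corrected by normexp with an offset of 50, on the mean signal and the median local background, and log ratios were then normalized within each array by loess with control spots at weight 0. No scaling between arrays was applied. Control spots and spots marked as outliers (8 to 301 per array) were left out, and 2370 log ratios (0.682%) were missing. The 21073 gene spots stood for 20173 probes and 18972 names. Spots of a probe were averaged, and of several probes of a name (1132 names) the brightest was used. A probe was kept when well above background (in at least 0.5 of its spots) in every channel of at least 1 condition, which left 15787 genes or transcripts, 12208 with a gene symbol. Of these 10689 were well above background in all 44 channels. Names were matched to current symbols by RefSeq accession (14892 probes), current symbol (366) or older symbol (196) in the gene table of assembly GRCh38.p14, used for names alone, and 4719 probes had no match. The files name no genome build, so no positions are given.

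The factorial fit held terms for line, drug series, day and their products of a pair, a treatment effect for each line and drug averaged over both days, and a gene-specific dye term (11 parameters, 11 residual degrees of freedom, prior 5.4). Changes of a response between 2 and 4 days came from a fit with a parameter for each condition (16 parameters with the dye term, 6 residual degrees of freedom, prior 6.39). Tests were limma's moderated tests, two-sided, with Benjamini-Hochberg adjustment over the genes tested in each of the 15 comparisons. Differences between lines, drugs and days were tested as contrasts of the same fit. Per the labels the arrays were hybridised in 3 batches, and an array's batch was read from the day of feature extraction in its file header. The 28 gene lists were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation beside it, and with fry. For camera, missing values were filled with those fitted. Correlations of responses are across genes, beside 100 simulations of unchanged genes with each gene's residual spread. The number of arrays limits the precision: the median standard error was 0.0636 for SAHA in DU-145 and 0.0899 for a difference of responses. Steps on simulated data with 100 changed genes of 15787 recovered 90% of log2 changes of 0.5 and 99% of changes of 1 for SAHA in DU-145, and 72% and 96% for its line difference. With no change put in, 0 genes were called in the 5 comparisons tested.

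Before the data were examined, the comparisons, lists and the rule for naming genes were fixed. So were the alternatives, except those named further on as chosen after the data were seen. For each treatment the rule took the 8 highest and 8 lowest changes with a symbol that were called, had the same sign at both days and were well above background in all channels of the treated or of the control cells, and the 2 largest called members of each list called. It took 5 per direction for differences and lines and 3 for time. CDKN1A (treatments) and CTNNA1 (lines) were named whatever their values. Some genes that the rule took are not reported here. Members named outside the rule were picked after their values were seen: B2M, HLA-F, HDAC1 and AKR1C3. Genes of the Y chromosome are left out.

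Alternatives were no background subtraction, processed signals, the value table, no filter, a stricter filter, the mean of a name's probes, no dye term, a dye term for each batch, tests without moderation, the fit with 16 conditions, a fit at the level of cultures, the 8 direct arrays alone, the 10 arrays within a drug series, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.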

Results

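RNA of cultured prostate cancer cells was compared on 22 two-colour oligonucleotide arrays. The cells were DU-145 and PC3, human prostate cancer lines. They were treated with SAHA (vorinostat), a hydroxamic acid, or with VPA (valproic acid), a short branched-chain fatty acid. Both drugs inhibit histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. The 2 lines, 2 drug series, treated or control cells and 2 time points (2 and 4 days) made 16 conditions, each with a single source name. Each array set 2 conditions against each other, 1 labelled with Cy5 and 1 with Cy3, and the arrays formed loops that linked all conditions. The series describes a study of resistance to these inhibitors in lines of differing sensitivity, and its comparisons ask how the responses differ by line, by drug and by time. Doses are not given in the sources used here.

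The arrays held 22153 spots each, of which 1080 were controls, and 15787 genes or transcripts passed the signal filter. The median spot signal lay between 89.52 and 153.1 for Cy5 and between 120.2 and 178.9 for Cy3, over a local background of 56 to 64. Between 65.34% and 80.93% of the spots were well above background in Cy5, and 65.67% to 78.47% in Cy3. Changes are log2 ratios with their standard error, so that 1 is a doubling, and a gene is called at an adjusted p under 0.05. Each treatment change equals exactly the mean of the 2 arrays (direct arrays) that set treated against control cells of that line and drug, at 2 and at 4 days and with opposite dyes. The other arrays supply the estimate of the spread. Where an outlier spot left 1 of these arrays without a value, the change is that of the other array corrected by the fitted dye term, as for ANGPTL4 and EBNA1BP2 after SAHA in DU-145, IL6, VIM and HSPD1 after SAHA in PC3, and KRT19 after VPA in PC3. Since each condition has a single source name, the p-values may measure mostly the spread between hybridisations. The 22 arrays fell into 3 hybridisation batches of 7, 8 and 7 arrays (A, B and C), and the 2 arrays behind each treatment change lay in a single batch: A for SAHA in PC3, C for SAHA in DU-145, and B for VPA in both lines. The pooled treatment changes are therefore within-batch values. The offset added to the signals compresses the changes of dim genes.

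SAHA in DU-145 cells raised HLA-DMB, a chain of the HLA-DM heterodimer that loads peptides onto MHC class II, by 2.67 ± 0.14 (6.37-fold, adjusted p = 1.4e-09). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 2.49 ± 0.29. SCG5 (SGNE1 in the files), a chaperone of secretory granules of neuroendocrine cells, rose by 2.19 ± 0.28. A dim probe of SCG5 showed no such change. SELENOP (SEPP1), a selenium transport protein, rose by 2.23 ± 0.25, against controls that were well above background in 0 of 4 channels, so that the size of its change is uncertain. Further increases were those of G0S2, an inhibitor of adipose triglyceride lipase (2.10 ± 0.15), of ANKRD1, a target of YAP signalling (2.03 ± 0.13), and of SPINK2, a serine protease inhibitor (2.03 ± 0.092).

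NPTX1, a neuronal pentraxin, fell by 1.35 ± 0.08 in SAHA-treated DU-145 cells, and LMNB1, a lamin of the nuclear envelope, changed by -1.26 ± 0.15. ADI1, an enzyme of methionine salvage, changed by -1.15 ± 0.11, the mitotic kinase PBK by -1.12 ± 0.10, FAM216A by -1.11 ± 0.093 and HMGN2P46 (C15orf21), a pseudogene of a nucleosome-binding protein, by -1.07 ± 0.10. CABLES1, a cyclin-dependent kinase adaptor, changed by -1.08 ± 0.075, and TRIP13, an ATPase of the spindle checkpoint, by -1.07 ± 0.068. ADI1, PBK, FAM216A, G0S2 and some genes named further on are listed in the files by a sequence accession alone and are given by their current symbol. In all, 4730 of 15761 genes were called, 2670 higher and 2060 lower, of which 140 were at least 2-fold higher and 13 at least 2-fold lower. Of the called genes 4704 had the same sign at both days. Such a share, here and in the other treatments, follows largely from the selection. A call rests on the mean of both days, with their disagreement counted as error. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.29 ± 0.20 (adjusted p = 0.00011). It was fixed as a label check, since it is known to rise with such inhibitors. Without the 4-day direct array, 2564 genes were called.

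Cell cycle genes fell as lists after SAHA in DU-145. Of the mitosis genes 0 rose, 42 fell and 3 of 45 were not called (0 and 43 adjusted over the list alone, median -0.54, adjusted p = 7.8e-29, and adjusted p = 0.0079 with an estimated correlation). The cyclin CCNB1 changed by -0.95 ± 0.11 and the spindle protein SPAG5 by -0.92 ± 0.066. Among genes of DNA replication 1 rose, 23 fell and 15 of 39 were not called (2 and 23 adjusted over the list alone, median -0.28, adjusted p = 3.2e-07, and adjusted p = 0.0066 with an estimated correlation). TYMS, thymidylate synthase, changed by -0.93 ± 0.049 and CDC45 (CDC45L), a helicase component, by -0.91 ± 0.070. For DNA repair genes 1 rose, 14 fell and 12 of 27 were not called (1 and 14 adjusted over the list alone, median -0.16, adjusted p = 2.8e-05, and adjusted p = 0.17 with an estimated correlation). The recombination gene RAD54L changed by -0.88 ± 0.073 and BRCA1 by -0.68 ± 0.059. Of the genes of ribosome biogenesis 2 rose, 24 fell and 4 of 30 were not called (2 and 24 adjusted over the list alone, median -0.33, adjusted p = 2.9e-08, and adjusted p = 0.034 with an estimated correlation), among them BOP1 (-0.80 ± 0.099) and EBNA1BP2 (-0.73 ± 0.14, from -0.50 on its lone direct array, with -0.17 at 2 days and -0.69 at 4 days in the fit with a parameter for each condition). In the heat shock list 2 rose, 9 fell and 12 of 23 were not called (2 and 9 adjusted over the list alone, median -0.16, adjusted p = 0.0037, and adjusted p = 0.26 with an estimated correlation). The mitochondrial chaperone HSPD1 changed by -0.82 ± 0.11 and AHSA1, an activator of HSP90, by -0.50 ± 0.066.

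Lists with more increases than decreases after SAHA in DU-145 began with antigen presentation, in which 11 rose, 0 fell and 10 of 21 were not called (12 and 0 adjusted over the list alone, median 0.48, adjusted p = 2.8e-05, and adjusted p = 0.18 with an estimated correlation). HLA-DPB1 rose by 1.57 ± 0.16, against controls well above background in 1 of 4 channels, and B2M, the light chain of MHC class I, by 0.85 ± 0.067. Of the metallothioneins, small metal-binding proteins, 4 rose, 0 fell and 5 of 9 were not called (6 and 0 adjusted over the list alone, median 0.48, adjusted p = 0.0065, and adjusted p = 0.33 with an estimated correlation). MT1F rose by 0.98 ± 0.073 and MT1G by 0.67 ± 0.21. Without either direct array MT1G was not called, at 0.60 and 0.75. Among cytokines, chemokines and NF-kappaB targets 12 rose, 1 fell and 11 of 24 were not called (12 and 1 adjusted over the list alone, median 0.38, adjusted p = 0.00062, and adjusted p = 0.26 with an estimated correlation). CXCL1 rose by 1.80 ± 0.17, with 0.95 on a second probe, and CCL20 by 1.44 ± 0.15. For epithelial adhesion and keratin genes 13 rose, 1 fell and 16 of 30 were not called (14 and 1 adjusted over the list alone, median 0.18, adjusted p = 0.00015, and adjusted p = 0.079 with an estimated correlation). KRT19, a keratin of simple epithelia, rose by 1.77 ± 0.14 and the tight junction gene CLDN7 by 1.76 ± 0.090. Of the mesenchymal markers 10 rose, 2 fell and 12 of 24 were not called (10 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.0065, and adjusted p = 0.26 with an estimated correlation), with increases of CCN2 (CTGF, 1.28 ± 0.20) and fibronectin FN1 (0.93 ± 0.22). FN1 was not called without the 4-day array (0.85). In the list of growth factors and their receptors 9 rose, 1 fell and 13 of 23 were not called (9 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.0018, and adjusted p = 0.081 with an estimated correlation). IGFBP3, a binding protein of insulin-like growth factors, rose by 1.29 ± 0.13 and TGFA by 0.97 ± 0.091, whose dim second probe gave 0.098.

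SAHA in PC3 cells raised KRTAP3-1, a keratin-associated protein of hair, by 2.38 ± 0.11 (5.22-fold, adjusted p = 6.3e-10). CXCL8 (IL8), a chemokine that attracts neutrophils, rose by 2.27 ± 0.33 and HLA-DMB by 1.97 ± 0.14. IL37 (IL1F7), a cytokine of the interleukin-1 family, rose by 2.08 ± 0.33. Increases were also measured for RNF182, a ubiquitin ligase (1.79 ± 0.064), NNMT, an enzyme that methylates nicotinamide (1.79 ± 0.14), and CRIP2, a LIM domain protein (1.78 ± 0.16). The neuropeptide galanin, GAL, changed by -2.14 ± 0.10, with -2.01 on its other probe, and LTB, a lymphotoxin, by -1.54 ± 0.22. ID1, an inhibitor of helix-loop-helix transcription factors, changed by -1.45 ± 0.42 (adjusted p = 0.021). MAP6D1, a microtubule-stabilising protein, changed by -1.18 ± 0.093, STMN3, a stathmin of neurons, by -1.09 ± 0.11, and CLMP, an adhesion molecule, by -1.08 ± 0.26. DMBT1, a secreted scavenger receptor protein, changed by -1.04 ± 0.11 and SCARB1, a receptor of high-density lipoprotein, by -1.01 ± 0.10, with -0.13 on a dim second probe.

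In PC3, SAHA changed 3212 of 15781 genes, 1830 higher and 1382 lower, with 73 at least 2-fold higher and 9 at least 2-fold lower. The sign was the same at both days for 3203 of them. CDKN1A rose by 0.74 ± 0.20 (adjusted p = 0.014). Without the 4-day direct array 1601 genes were called, and without that at 2 days 2065. Without the 4-day array IL37 (1.32), ID1 (-0.47), CLMP (-0.64) and CDKN1A (0.46) were not called.

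The list of ribosome biogenesis genes moved most clearly after SAHA in PC3, where 1 rose, 19 fell and 10 of 30 were not called (1 and 24 adjusted over the list alone, median -0.27, adjusted p = 2.7e-09, and adjusted p = 0.061 with an estimated correlation). ODC1, ornithine decarboxylase, changed by -0.71 ± 0.055 and CAD, an enzyme of pyrimidine synthesis, by -0.55 ± 0.064. Of the DNA replication genes 0 rose, 8 fell and 31 of 39 were not called (0 and 8 adjusted over the list alone, median -0.067, adjusted p = 0.0077, and adjusted p = 0.13 with an estimated correlation), with UNG, uracil-DNA glycosylase, at -0.56 ± 0.085 and MCM5 at -0.40 ± 0.073. MCM5 was not called without the 4-day array (-0.32). The mitosis list was not called in this comparison: 1 gene rose, 6 fell and 38 were not called, with a median of -0.072 and adjusted p = 0.074. Among heat shock genes 1 rose, 7 fell and 15 of 23 were not called (1 and 8 adjusted over the list alone, median -0.12, adjusted p = 0.0045, and adjusted p = 0.24 with an estimated correlation). HSPD1 changed by -0.86 ± 0.16 and HSP90AA1 (HSPCA), an HSP90 chaperone, by -0.60 ± 0.094. Growth arrest genes and cyclin-dependent kinase inhibitors went up, in that 6 rose, 0 fell and 9 of 15 were not called (6 and 0 adjusted over the list alone, median 0.13, adjusted p = 0.011, and adjusted p = 0.15 with an estimated correlation). BTG1, an antiproliferative gene, rose by 0.67 ± 0.088. For inhibitors of apoptosis 4 rose, 0 fell and 7 of 11 were not called (4 and 0 adjusted over the list alone, median 0.083, adjusted p = 0.031, and adjusted p = 0.24 with an estimated correlation). BCL2A1 rose by 1.73 ± 0.14 and BIRC3 by 1.03 ± 0.15.

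For the metallothioneins in SAHA-treated PC3 cells 7 rose, 0 fell and 2 of 9 were not called (7 and 0 adjusted over the list alone, median 0.69, adjusted p = 0.0023, and adjusted p = 0.24 with an estimated correlation). MT2A rose by 0.89 ± 0.28 and MT1G by 0.74 ± 0.21. Without the 4-day array MT2A (0.57) and MT1G (0.39) were not called, nor was MT2A without the 2-day array (1.21). Of the antigen presentation genes 8 rose, 0 fell and 13 of 21 were not called (8 and 0 adjusted over the list alone, median 0.14, adjusted p = 0.00016, and adjusted p = 0.24 with an estimated correlation), and HLA-B rose by 0.86 ± 0.12. Of the interferon-stimulated genes 6 rose, 0 fell and 18 of 24 were not called (6 and 0 adjusted over the list alone, median 0.09, adjusted p = 0.011, and adjusted p = 0.24 with an estimated correlation). IFIT1 rose by 0.70 ± 0.13, not called without the 4-day array (0.53), and the exonuclease ISG20 by 0.60 ± 0.079. Cytokines, chemokines and NF-kappaB targets gave a count in which 13 rose, 2 fell and 9 of 24 were not called (13 and 3 adjusted over the list alone, median 0.44, adjusted p = 0.0023, and adjusted p = 0.24 with an estimated correlation). The cytokine IL6 rose by 1.41 ± 0.21.

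Structural gene lists were also called after SAHA in PC3. Of the epithelial genes 9 rose, 1 fell and 20 of 30 were not called (9 and 1 adjusted over the list alone, median 0.17, adjusted p = 0.00057, and adjusted p = 0.13 with an estimated correlation). KRT19 rose by 1.29 ± 0.14 and CLDN4 by 0.91 ± 0.054. Of the mesenchymal markers in PC3 6 rose, 1 fell and 17 of 24 were not called (6 and 1 adjusted over the list alone, median 0.055, adjusted p = 0.031, and adjusted p = 0.31 with an estimated correlation). Vimentin, VIM, rose by 2.17 ± 0.32 and FN1 by 1.45 ± 0.22. Among actin-binding and tubulin genes 9 rose, 1 fell and 14 of 24 were not called (9 and 2 adjusted over the list alone, median 0.16, adjusted p = 0.0083, and adjusted p = 0.35 with an estimated correlation). TMSB10, a thymosin, rose by 0.89 ± 0.083 and LCP1, an actin-bundling protein, by 0.63 ± 0.19. LCP1 was not called without either direct array (0.51 and 0.75).

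VPA in DU-145 cells raised HLA-DMB by 3.02 ± 0.14 (8.14-fold, adjusted p = 2.4e-10). SCG5 rose by 2.67 ± 0.28, with no change on its dim probe, and FXYD6, a regulator of the sodium pump, by 2.64 ± 0.13. SELENOP rose by 2.55 ± 0.25, against controls well above background in 1 of 4 channels, and ANGPTL4 by 2.17 ± 0.20. VGF, a neuropeptide precursor, rose by 2.38 ± 0.13 and MMP1, a collagenase, by 2.35 ± 0.34. NNMT changed by -1.26 ± 0.14, CABLES1 by -1.14 ± 0.075, LMNB1 by -1.07 ± 0.15, ADI1 by -1.06 ± 0.11 and FAM216A by -1.01 ± 0.093. Decreases were also measured for WDR4, a subunit of a tRNA methyltransferase (-1.06 ± 0.082), the apoptosis inhibitor AVEN (-1.04 ± 0.082) and RCC1 (CHC1), the exchange factor of Ran (-1.03 ± 0.10).

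Of 15787 genes, VPA changed 5108 in DU-145, 3009 higher and 2099 lower, with 197 at least 2-fold higher and 9 at least 2-fold lower. The sign at 2 and 4 days was the same for 5101. CDKN1A rose by 1.23 ± 0.20 (adjusted p = 0.00014). Without the 4-day direct array 2638 genes were called.

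Mitosis genes fell after VPA in DU-145, where 0 rose, 36 fell and 9 of 45 were not called (0 and 39 adjusted over the list alone, median -0.40, adjusted p = 3.6e-19, and adjusted p = 0.023 with an estimated correlation). CCNB1 changed by -0.76 ± 0.11 and the cyclin CCNA2 by -0.73 ± 0.050. Replication genes followed, and 1 rose, 22 fell and 16 of 39 were not called (3 and 22 adjusted over the list alone, median -0.26, adjusted p = 9.2e-08, and adjusted p = 0.0048 with an estimated correlation). TYMS changed by -0.91 ± 0.049 and CDC45 by -0.79 ± 0.070. Of the DNA repair genes 1 rose, 16 fell and 10 of 27 were not called (1 and 16 adjusted over the list alone, median -0.19, adjusted p = 3.1e-06, and adjusted p = 0.13 with an estimated correlation). RAD54L changed by -0.74 ± 0.073. In the list of ribosome biogenesis 1 rose, 26 fell and 3 of 30 were not called (1 and 27 adjusted over the list alone, median -0.38, adjusted p = 4.5e-12, and adjusted p = 0.013 with an estimated correlation). DKC1, a pseudouridine synthase, changed by -0.86 ± 0.082 and nucleophosmin, NPM1, by -0.84 ± 0.070. Of the heat shock genes 2 rose, 11 fell and 10 of 23 were not called (2 and 12 adjusted over the list alone, median -0.20, adjusted p = 0.0031, and adjusted p = 0.27 with an estimated correlation). HSPD1 changed by -0.69 ± 0.11 and HSP90AA1 by -0.55 ± 0.094, the latter not called without the 4-day array (-0.38).

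Increases after VPA in DU-145 included the antigen presentation list, in which 14 rose, 0 fell and 7 of 21 were not called (16 and 0 adjusted over the list alone, median 0.54, adjusted p = 1.1e-06, and adjusted p = 0.13 with an estimated correlation). HLA-DPB1 rose by 1.63 ± 0.16, against controls well above background in 1 of 4 channels, and HLA-F by 1.05 ± 0.10. Of the interferon-stimulated genes in DU-145 11 rose, 0 fell and 13 of 24 were not called (11 and 0 adjusted over the list alone, median 0.054, adjusted p = 0.028, and adjusted p = 0.29 with an estimated correlation), with IFIT1 at 0.98 ± 0.13 and IFI6 (G1P3) at 0.85 ± 0.12. For the metallothioneins 7 rose, 0 fell and 2 of 9 were not called (8 and 0 adjusted over the list alone, median 0.61, adjusted p = 0.0031, and adjusted p = 0.29 with an estimated correlation). MT1F rose by 1.15 ± 0.073 and MT1G by 0.76 ± 0.21, and without either direct array MT1G was not called (0.68 and 0.84). Cytokine and NF-kappaB target genes were called as well, and 9 rose, 1 fell and 14 of 24 were not called (9 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.006, and adjusted p = 0.29 with an estimated correlation). CXCL1 rose by 1.69 ± 0.17, with 0.89 on a second probe, and CCL20 by 1.59 ± 0.15. Of the epithelial genes in DU-145 12 rose, 2 fell and 16 of 30 were not called (13 and 2 adjusted over the list alone, median 0.14, adjusted p = 0.0031, and adjusted p = 0.13 with an estimated correlation). CLDN7 rose by 2.14 ± 0.090 and KRT19 by 1.49 ± 0.14. Genes normally restricted to neurons or neuroendocrine cells were called after VPA, as 11 rose, 0 fell and 18 of 29 were not called (11 and 0 adjusted over the list alone, median 0.14, adjusted p = 0.0097, and adjusted p = 0.27 with an estimated correlation). Among promoters of apoptosis 10 rose, 2 fell and 8 of 20 were not called (10 and 3 adjusted over the list alone, median 0.19, adjusted p = 0.031, and adjusted p = 0.13 with an estimated correlation). PMAIP1, or NOXA, rose by 0.63 ± 0.092 and BIK by 0.62 ± 0.074, whose dim second probe gave 0.028.

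VPA in PC3 cells raised CXCL8 by 2.92 ± 0.33 (7.59-fold, adjusted p = 2.1e-05), with 1 saturated channel, and KRTAP3-1 by 2.55 ± 0.11. BCL2A1, an inhibitor of apoptosis, rose by 2.26 ± 0.14, and ESM1, a proteoglycan of endothelial cells, by 2.14 ± 0.31. IL37 rose by 2.02 ± 0.33 and RNF182 by 1.98 ± 0.064. IL1R2, a decoy receptor of interleukin-1, rose by 1.92 ± 0.27. ID1 changed by -1.73 ± 0.42 (adjusted p = 0.0063), GAL by -1.51 ± 0.10 and LTB by -1.42 ± 0.22. KLK6, a kallikrein protease, changed by -1.35 ± 0.17, SCARB1 by -0.99 ± 0.10 and STMN3 by -0.95 ± 0.11. NPM3, a nucleoplasmin, changed by -0.97 ± 0.16 and DRC8, a ciliary protein, by -0.96 ± 0.085.

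The VPA response of PC3 comprised 3492 of 15787 genes, 1931 higher and 1561 lower, and 76 were at least 2-fold higher. The sign at both days was the same for 3483. CDKN1A rose by 1.04 ± 0.20 (adjusted p = 0.0012). Without the 4-day direct array 1804 genes were called, and without that at 2 days 1922. ID1 (-1.02) and CDKN1A (0.85) were not called without the 4-day array, nor was NPM3 (-0.66) without the 2-day array.

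Ribosome biogenesis genes fell after VPA in PC3, where 1 rose, 25 fell and 4 of 30 were not called (1 and 25 adjusted over the list alone, median -0.36, adjusted p = 1e-12, and adjusted p = 0.013 with an estimated correlation). The nucleolar protein NCL changed by -0.65 ± 0.085 and NPM1 by -0.64 ± 0.070. Among the DNA replication genes in PC3 1 rose, 15 fell and 23 of 39 were not called (2 and 19 adjusted over the list alone, median -0.16, adjusted p = 3.2e-05, and adjusted p = 0.013 with an estimated correlation). UNG changed by -0.76 ± 0.085 and the helicase subunit MCM4 by -0.52 ± 0.084. In the mitosis list 2 rose, 6 fell and 37 of 45 were not called (2 and 5 adjusted over the list alone, median -0.11, adjusted p = 0.018, and adjusted p = 0.44 with an estimated correlation). CCNA2 changed by -0.34 ± 0.050 and the transcription factor FOXM1 by -0.31 ± 0.059. Of the DNA repair genes in PC3 1 rose, 6 fell and 20 of 27 were not called (1 and 7 adjusted over the list alone, median -0.089, adjusted p = 0.013, and adjusted p = 0.35 with an estimated correlation), with RAD54L at -0.44 ± 0.073 and MSH6, of mismatch repair, at -0.36 ± 0.071. Among the heat shock genes in PC3 1 rose, 8 fell and 14 of 23 were not called (1 and 11 adjusted over the list alone, median -0.15, adjusted p = 0.0062, and adjusted p = 0.32 with an estimated correlation). HSP90AA1 changed by -0.69 ± 0.094 and HSPD1 by -0.55 ± 0.11. Genes of cholesterol synthesis were called lower, and 1 rose, 6 fell and 17 of 24 were not called (1 and 6 adjusted over the list alone, median -0.11, adjusted p = 0.028, and adjusted p = 0.32 with an estimated correlation). SREBF1, a sterol response factor, changed by -0.65 ± 0.11 and DHCR7 by -0.38 ± 0.070. Histone genes with polyadenylated or replication-independent transcripts were called lower, and 1 rose, 5 fell and 19 of 25 were not called (1 and 8 adjusted over the list alone, median -0.15, adjusted p = 0.028, and adjusted p = 0.25 with an estimated correlation). H2AJ (H2AFJ) rose by 0.64 ± 0.15 and H1-4 (HIST1H1E) changed by -0.36 ± 0.095. Without the 2-day array MSH6 (-0.23), HSPD1 (-0.28), DHCR7 (-0.23), H2AJ (0.35) and H1-4 (-0.21) were not called.

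Among the cytokines, chemokines and NF-kappaB targets of VPA-treated PC3 cells 14 rose, 2 fell and 8 of 24 were not called (15 and 2 adjusted over the list alone, median 0.82, adjusted p = 3.8e-07, and adjusted p = 0.16 with an estimated correlation). The cytokine IL1B rose by 1.82 ± 0.23, with 2 saturated channels. Of the antigen presentation genes in PC3 8 rose, 0 fell and 13 of 21 were not called (10 and 0 adjusted over the list alone, median 0.20, adjusted p = 6.1e-05, and adjusted p = 0.25 with an estimated correlation). HLA-DMB rose by 1.38 ± 0.14 and HLA-C by 0.80 ± 0.11. Metallothioneins rose, and 6 rose, 0 fell and 3 of 9 were not called (7 and 0 adjusted over the list alone, median 0.77, adjusted p = 0.0024, and adjusted p = 0.32 with an estimated correlation). MT2A rose by 0.93 ± 0.28 and MT1B by 0.84 ± 0.22. For the growth arrest and cyclin-dependent kinase inhibitor list 6 rose, 0 fell and 9 of 15 were not called (7 and 0 adjusted over the list alone, median 0.088, adjusted p = 0.018, and adjusted p = 0.18 with an estimated correlation). CDKN2D, or p19, rose by 1.11 ± 0.099. Without the 4-day array MT2A (0.23) and MT1B (0.43) were not called.

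Of the epithelial genes in VPA-treated PC3 cells 8 rose, 1 fell and 21 of 30 were not called (8 and 1 adjusted over the list alone, median 0.044, adjusted p = 0.048, and adjusted p = 0.32 with an estimated correlation). CLDN1 rose by 0.90 ± 0.19 and KRT19 by 0.79 ± 0.21. The epithelial list was not called without background subtraction (adjusted p = 0.05), in the deposited value table (0.061) or with the processed signals of the scanner software (0.055). With the processed signals the lists of mesenchymal markers, cholesterol synthesis and cyclin-dependent kinase inhibitors were not called either. For the mesenchymal markers 7 rose, 0 fell and 17 of 24 were not called (7 and 0 adjusted over the list alone, median 0.034, adjusted p = 0.039, and adjusted p = 0.35 with an estimated correlation). FN1 rose by 1.18 ± 0.22 and VIM by 0.81 ± 0.22. Among actin-binding and tubulin genes in PC3 9 rose, 3 fell and 12 of 24 were not called (10 and 3 adjusted over the list alone, median 0.15, adjusted p = 0.035, and adjusted p = 0.44 with an estimated correlation). TMSB10 rose by 0.96 ± 0.083 and LCP1 by 0.67 ± 0.19. Without the 4-day array CLDN1 (0.45), FN1 (0.89), VIM (0.31) and LCP1 (0.54) were not called, nor was LCP1 without the 2-day array (0.79).

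Of the 28 lists fixed beforehand, 11 were called after SAHA in DU-145, 12 after SAHA in PC3, 12 after VPA in DU-145 and 14 after VPA in PC3. Of these 49 calls, 8 held when the correlation between a list's genes was estimated: DNA replication, mitosis and ribosome biogenesis in DU-145 with either drug, and DNA replication and ribosome biogenesis in PC3 with VPA. All 49 were also called by a test of whether a list's genes moved on balance in 1 direction, which does not compare a list with other genes and called 82 of the 112 pairs of list and treatment. In 9 lists no treatment gave a call. For histone deacetylases and acetyltransferases the adjusted p ran from 0.086 to 0.63, although HDAC1 rose in all 4 treatments, by 0.68 ± 0.11 and 0.23 ± 0.077 after SAHA in DU-145 and PC3 and by 0.86 ± 0.077 and 0.37 ± 0.077 after VPA. For genes of oxidative stress the adjusted p ran from 0.31 to 0.68, with AKR1C3, an aldo-keto reductase, higher by 1.40 ± 0.097 and 0.93 ± 0.097 after SAHA and by 1.58 ± 0.097 and 0.99 ± 0.097 after VPA. It ran from 0.12 to 0.55 for androgen receptor and prostate secretory genes, from 0.058 to 1 for the unfolded protein response, and from 0.56 to 0.81 for glycolysis and hypoxia. For cancer-testis antigens it ran from 0.65 to 0.91, and for drug transporters from 0.48 to 1. Markers of fibroblasts and endothelial cells (0.44 to 0.89) and of white blood cells (0.68 to 1), cell types the cultures should lack, were not called. The members HDAC1 and AKR1C3 were picked after their values were seen.

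**Figure D1:**
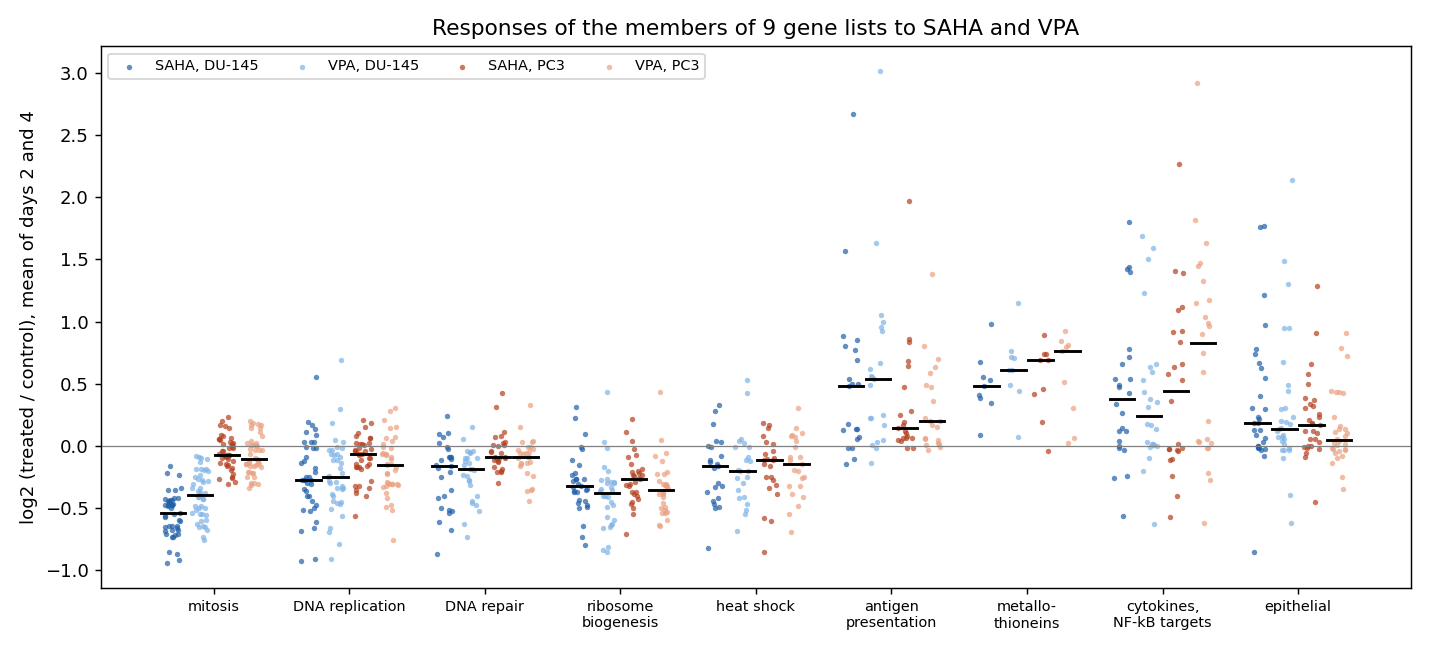
Log2 change, treated over control, of the measured members of 9 gene lists in the 4 treatments, as the mean of 2 and 4 days. Points are genes and black lines are medians, and the mitosis medians are -0.54 and -0.40 in DU-145 after SAHA and VPA against -0.072 and -0.11 in PC3.

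**Figure D2:**
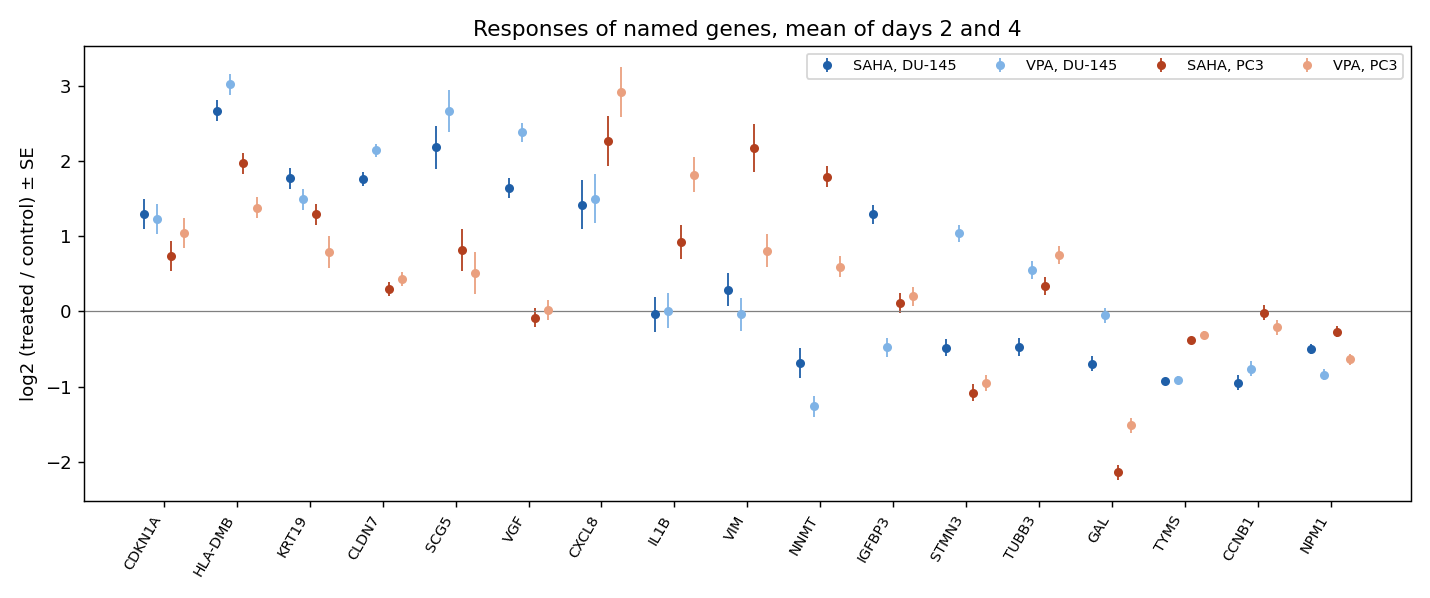
Log2 change, treated over control, of 17 named genes in the 4 treatments. Error bars are standard errors, and values above 0 are higher in treated cells.

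Responses of the 2 lines to the same drug were compared by their difference, PC3 minus DU-145. Responses are signed, so a higher value in PC3 can also stand beside a decrease in DU-145. After SAHA, the response was higher in PC3 for NNMT by 2.47 ± 0.25 (adjusted p = 2.7e-05) and for KRTAP3-1 by 2.44 ± 0.15. It was also higher for VIM by 1.89 ± 0.38, for IL37 by 2.07 ± 0.46 and for ADAM8, a membrane metalloprotease, by 1.34 ± 0.13. ANGPTL4 had a lower response in PC3, with a difference of -2.14 ± 0.35, as had CST6, a cystatin protease inhibitor (-2.02 ± 0.15), SUSD3, a sushi domain protein (-1.84 ± 0.12), the cytokine receptor subunit IL20RB (-1.73 ± 0.13) and VGF (-1.73 ± 0.19). The difference was called for 1718 of 15755 genes, 776 with a higher and 942 with a lower value in PC3. Without the 4-day direct arrays 919 (of DU-145) or 1059 (of PC3) were called. IL37 was not called without the 4-day array of PC3 (1.31) or the 2-day array of DU-145 (2.00), nor was VIM without the latter (1.69). The SAHA arrays of the 2 lines lay in different batches (A and C), so that batch and line cannot be told apart in this comparison.

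The mitosis list differed most between the lines after SAHA: 38 of 45 were higher and 0 lower (39 and 0 adjusted over the list alone, median 0.50, adjusted p = 2e-32, and adjusted p = 0.0099 with an estimated correlation), so that these genes fell less in PC3. For DNA replication 11 of 39 were higher and 2 lower (12 and 2 adjusted over the list alone, median 0.15, adjusted p = 0.00052, and adjusted p = 0.032 with an estimated correlation). In the DNA repair list 9 of 27 were higher and 1 lower (12 and 2 adjusted over the list alone, median 0.12, adjusted p = 0.00052, and adjusted p = 0.48 with an estimated correlation). Actin-binding and tubulin genes were called, and 4 of 24 were higher and 2 lower (6 and 3 adjusted over the list alone, median 0.16, adjusted p = 0.034, and adjusted p = 0.8 with an estimated correlation). For growth factors and receptors 0 of 23 were higher and 5 lower (0 and 5 adjusted over the list alone, median -0.083, adjusted p = 0.0054, and adjusted p = 0.16 with an estimated correlation). With an estimated correlation the mitosis and DNA replication calls held. The call of actin-binding and tubulin genes was lost with the processed signals.

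The VPA response was higher in PC3 for IL37 (1.93 ± 0.46), NNMT (1.86 ± 0.20, adjusted p = 3.8e-05), IL1R2 (1.47 ± 0.38), the interleukin subunit IL23A (1.20 ± 0.26) and COXFA4L3 (1.20 ± 0.14), a mitochondrial protein. It was lower in PC3 for VGF (-2.36 ± 0.19), SUSD3 (-2.20 ± 0.12), SCG5 (-2.15 ± 0.39), STMN3 (-2.00 ± 0.16) and AIF1L (C9orf58), an actin-binding protein (-1.82 ± 0.11). The difference was called for 1672 of 15787 genes, 575 with a higher and 1097 with a lower value in PC3, and these values come from a single batch. Without the 4-day array of DU-145 751 genes were called, and without the 2-day array of PC3 1007. IL37, IL1R2 and IL23A were not called without the 4-day array of PC3 (1.35, 1.02 and 1.01) or the 2-day array of DU-145 (1.93, 1.46 and 1.10), nor were IL37 (1.93) and IL1R2 (1.49) without the 4-day array of DU-145.

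For VPA too the mitosis genes fell less in PC3, and 25 of 45 were higher and 0 lower (32 and 0 adjusted over the list alone, median 0.33, adjusted p = 2.2e-19, and adjusted p = 0.067 with an estimated correlation). Of the DNA replication genes 5 of 39 were higher and 0 lower (5 and 0 adjusted over the list alone, median 0.093, adjusted p = 0.021, and adjusted p = 0.24 with an estimated correlation). Of the DNA repair genes 5 of 27 were higher and 1 lower (7 and 2 adjusted over the list alone, median 0.11, adjusted p = 0.0051, and adjusted p = 0.52 with an estimated correlation). In the list of neuronal genes 0 of 29 were higher and 5 lower (0 and 5 adjusted over the list alone, median -0.067, adjusted p = 0.025, and adjusted p = 0.52 with an estimated correlation). For antigen presentation 0 of 21 were higher and 4 lower (0 and 5 adjusted over the list alone, median -0.19, adjusted p = 0.019, and adjusted p = 0.52 with an estimated correlation). Cytokines and NF-kappaB targets were called higher in PC3, and 7 of 24 were higher and 1 lower (8 and 2 adjusted over the list alone, median 0.083, adjusted p = 0.021, and adjusted p = 0.52 with an estimated correlation). This call and that of the neuronal genes were lost with the processed signals, the latter also without the signal filter.

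SAHA and VPA were compared at matched times within each line, with each drug against its own controls. In DU-145, IGFBP3 rose with SAHA and fell with VPA (1.29 and -0.48), a difference of 1.77 ± 0.18 (adjusted p = 0.00018). STMN3 went the other way (-0.48 and 1.04), a difference of -1.53 ± 0.16, as did TUBB3, a tubulin of neurons (-0.47 and 0.55), with -1.03 ± 0.17. The SAHA response was also higher for KLRC2, a receptor of natural killer cells (1.09 ± 0.19), OGFRL1 (0.88 ± 0.12) and ERBIN (ERBB2IP), an adaptor of ERBB2 (0.87 ± 0.14). It was lower for the neuronal pentraxin NPTX2 (-1.11 ± 0.095), OGDHL, a mitochondrial dehydrogenase (-0.99 ± 0.11) and NGEF, an exchange factor of neurons (-0.98 ± 0.13). In all 355 of 15761 genes differed, 100 with a higher and 255 with a lower SAHA response. Without 1 of the direct arrays 42 (VPA, 4 days), 43 (SAHA, 4 days), 195 (SAHA, 2 days) or 207 (VPA, 2 days) differed. KLRC2 was not called without the 4-day array of SAHA (0.83) or those of VPA at 4 and 2 days (1.18 and 1.01), nor ERBIN (0.70) without the 4-day array of VPA, nor TUBB3 without that array (-0.77) or the 2-day array of SAHA (-0.89).

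Lists called in the drug difference of DU-145 were mitosis, of which 0 of 45 were higher and 1 lower (0 and 1 adjusted over the list alone, median -0.17, adjusted p = 1.8e-05, and adjusted p = 0.74 with an estimated correlation), and neuronal genes, of which 0 of 29 were higher and 2 lower (0 and 4 adjusted over the list alone, median -0.08, adjusted p = 0.037, and adjusted p = 0.74 with an estimated correlation). For ribosome biogenesis 1 of 30 were higher and 0 lower (3 and 0 adjusted over the list alone, median 0.11, adjusted p = 0.013, and adjusted p = 0.74 with an estimated correlation). Between SAHA-treated and VPA-treated DU-145 cells 656 genes differed, and between the controls of the 2 drug series limma called 0 genes (218 of 15749 at an unadjusted p under 0.05). No array held controls of both series, so their difference was reached through the treated cells. The unadjusted count is below what unchanged genes would give. The 0 therefore does not show that the controls were alike. STMN3 differed by -1.25 between treated cells and by 0.28 between the controls, IGFBP3 by 1.40 and -0.37, NPTX2 by -1.01 and 0.099 and NGEF by -0.79 and 0.19. TUBB3 was not called between treated cells (-0.87, adjusted p = 0.1), with 0.15 between the controls, and had no value on the array of VPA-treated against SAHA-treated cells.

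In PC3 10 of 15781 genes differed between the SAHA and VPA responses. KRT6B, a keratin, had a higher SAHA response by 1.16 ± 0.16 (adjusted p = 0.0042), as had APOBEC3B, a cytidine deaminase (1.09 ± 0.12, adjusted p = 0.00085), the gelatinase MMP9 (0.94 ± 0.15) and SLITRK6, a neuronal membrane protein (0.60 ± 0.099). The chemokine CXCL2 had a lower one (-0.75 ± 0.11), as had PTGS2, a cyclooxygenase (-0.68 ± 0.088), BTBD6 (-0.50 ± 0.069) and PLA2G4A, a phospholipase (-0.49 ± 0.086). The other 2 were sequences without a gene symbol. An unadjusted p under 0.05 was reached by 1006 genes. The median standard error of the difference was 0.0899 over all genes tested, so small differences would have been missed. Without single direct arrays 5 (SAHA at 4 days, and VPA at 2 or 4 days) or 16 genes (SAHA at 2 days) were called. APOBEC3B was called without any single array. Without the 4-day array of SAHA the difference was 0.98 for KRT6B, 0.64 for MMP9, -0.81 for CXCL2, -0.56 for PTGS2, -0.51 for BTBD6 and -0.47 for PLA2G4A, and none of these was called. KRT6B (1.03), MMP9 (0.77) and CXCL2 (-0.80) were not called without the 2-day array of VPA, nor were CXCL2 (-0.70), PTGS2 (-0.58) and BTBD6 (-0.46) without that at 4 days. CXCL2 was also lost without the 2-day array of SAHA (-0.70), as was SLITRK6 (0.47). Counting every array, the call of PLA2G4A ended without any of 16, that of SLITRK6 without any of 7 and that of MMP9 without any of 6.

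Among the lists in PC3, cytokines and NF-kappaB targets were called lower with SAHA than with VPA, and 0 of 24 were higher and 2 lower (0 and 3 adjusted over the list alone, median -0.13, adjusted p = 2.2e-06, and adjusted p = 0.29 with an estimated correlation). For DNA replication 0 of 39 were higher and 0 lower (0 and 0 adjusted over the list alone, median 0.059, adjusted p = 0.02, and adjusted p = 0.29 with an estimated correlation). For epithelial genes 0 of 30 were higher and 0 lower (2 and 0 adjusted over the list alone, median 0.083, adjusted p = 0.02, and adjusted p = 0.43 with an estimated correlation). The controls of the 2 series differed in 0 genes by limma (434 of 15771 at an unadjusted p under 0.05), and SAHA-treated and VPA-treated PC3 cells in 81. As in DU-145, the controls were compared through treated cells, and the 0 does not show that they were alike.

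Across genes, the responses to SAHA and VPA correlated in DU-145 with Pearson's r = 0.845 over the genes tested in both (15761), and with r = 0.841 and Spearman's rho = 0.723 over the 14404 genes measured on all arrays. In PC3 the values were r = 0.851 over 15781 genes, and r = 0.85 and rho = 0.718 over the 14404. For the same drug in the 2 lines r was lower, 0.553 for SAHA (0.545, rho = 0.489) and 0.593 for VPA (0.58, rho = 0.563). Unchanged genes simulated under the same design gave at most r = 0.0358. These correlations are across genes, which are not independent replicates, and only that of the VPA responses lies within a single batch. In DU-145 2020 genes rose with both drugs (509 for independent lists), 1365 fell with both (273) and 26 went opposite ways. In PC3 1342 rose with both (224), 966 fell with both (137) and 4 went opposite ways. With SAHA 1053 genes rose in both lines (309), 803 fell in both (180) and 119 were opposite, and with VPA 1256 rose (368), 941 fell (208) and 106 were opposite.

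**Figure D3:**
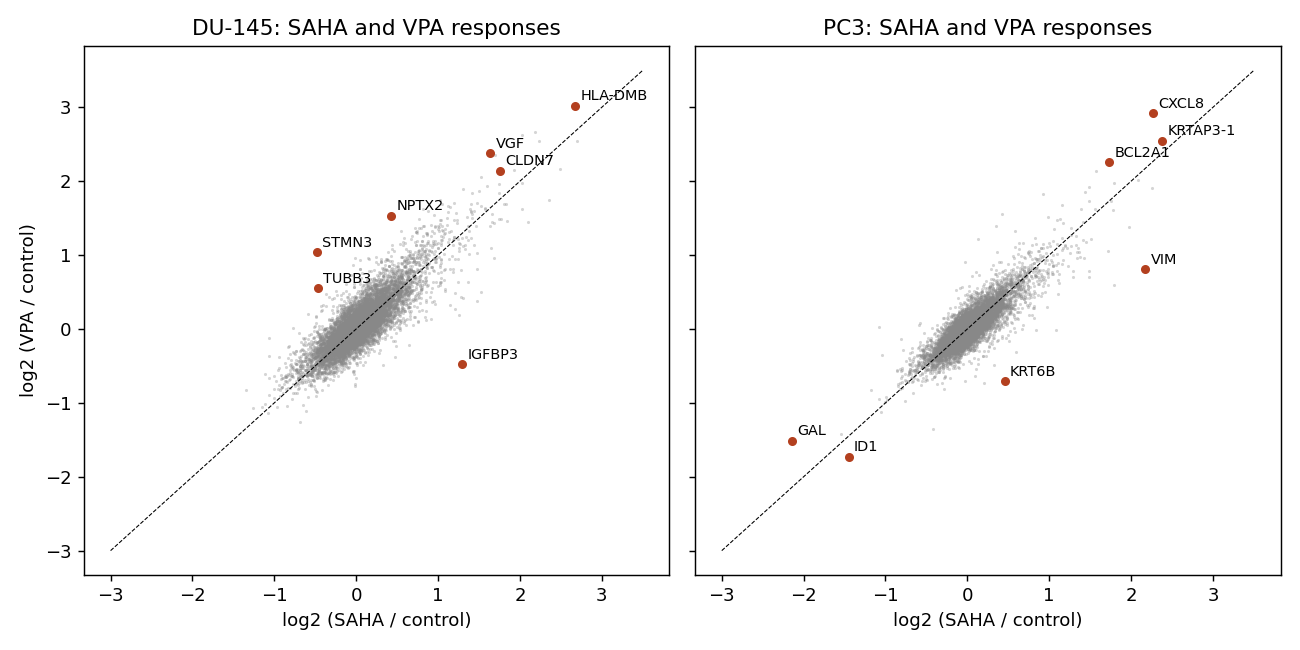
Log2 change after VPA against that after SAHA, treated over control, for each gene in DU-145 and in PC3, with the dashed line of equal change. The points correlate with r = 0.845 in DU-145 and r = 0.851 in PC3, and some genes named in the text are in red.

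Control cells of the 2 lines were compared through the loops, since no array held controls of both. MAL2, a protein of epithelial transcytosis, was higher in PC3 by 6.25 ± 0.091 (adjusted p = 1e-15), ALDH1A3, a retinaldehyde dehydrogenase, by 5.59 ± 0.10, IL1B by 5.34 ± 0.28 (well above background in 2 of 8 DU-145 channels), the chemokine CXCL5 by 5.22 ± 0.26 and the activin subunit INHBA by 4.98 ± 0.17. UCHL1, a ubiquitin hydrolase of neurons, was lower in PC3 (-5.64 ± 0.12, with 1 saturated channel, and well above background in 2 of 8 PC3 channels), as were MT1M (MT1K), a metallothionein (-5.36 ± 0.11, with -0.069 on a dim probe), and the tubulin TUBB6 (-4.59 ± 0.076). A pair of genes of the Y chromosome that the naming rule took are not reported. CTNNA1, a catenin gene deleted in PC3, served as a label check, and was lower in PC3 (-3.29 ± 0.072), where it was well above background in 0 of 8 channels, so that the size of the difference is uncertain. In all 7308 of 15752 genes differed, 3741 higher and 3567 lower in PC3, and no single array left out brought the count under 6720. Within 1 batch the comparison can be made for the VPA series alone, in batch B, where 7122 of these genes gave a slope of 1.02 on the values from all arrays. These arrays are among those behind the comparison, and none were left over for an error.

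Between the untreated lines, metallothioneins were lower in PC3, and 0 of 9 were higher and 8 lower (0 and 8 adjusted over the list alone, median -1.50, adjusted p = 0.00051, and adjusted p = 0.55 with an estimated correlation). Of the ribosome biogenesis genes 16 of 30 were higher and 1 lower (16 and 2 adjusted over the list alone, median 0.34, adjusted p = 0.0042, and adjusted p = 0.55 with an estimated correlation). Mitosis genes were called lower in PC3, and 6 of 45 were higher and 24 lower (6 and 25 adjusted over the list alone, median -0.24, adjusted p = 0.0042, and adjusted p = 0.55 with an estimated correlation). For cytokines and NF-kappaB targets 13 of 24 were higher and 4 lower (16 and 4 adjusted over the list alone, median 0.79, adjusted p = 0.0042, and adjusted p = 0.55 with an estimated correlation). For actin-binding and tubulin genes 4 of 24 were higher and 12 lower (4 and 12 adjusted over the list alone, median -0.28, adjusted p = 0.011, and adjusted p = 0.55 with an estimated correlation).

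Time in culture was compared as 4 days minus 2 days with treatment held, over both drug series. In DU-145 HMOX1, haem oxygenase, was lower at 4 days (-1.02 ± 0.081, adjusted p = 2.3e-05), as were ANGPTL4 (-0.84 ± 0.13) and the cytokine CSF2 (-0.39 ± 0.080). BANP, a nuclear matrix protein, was higher (0.52 ± 0.071), as were CCN5 (WISP2), a matricellular protein (0.46 ± 0.092), and the transcription factor KLF6 (COPEB, 0.46 ± 0.087). In all 160 of 15786 genes were called, 89 higher and 71 lower. Without the array of VPA-treated cells at 4 against 2 days 23 were called, and ANGPTL4 (-0.83), CSF2 (-0.42), CCN5 (0.35) and KLF6 (0.50) were not. Without the array of SAHA-treated cells at 2 against 4 days 49 were called, and CSF2 (-0.43), CCN5 (0.50) and KLF6 (0.32) were not. With 1 of 3 other arrays left out the count was 71, 71 or 74, and CSF2, CCN5 and KLF6 were also lost without certain other arrays.

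In PC3 S100A9, a calcium-binding protein of myeloid cells and stressed epithelia, was higher at 4 days (1.20 ± 0.19), as were DMBT1 (0.94 ± 0.068, adjusted p = 2.9e-06) and the transcription factor BHLHE41 (BHLHB3, 0.86 ± 0.11). IL6 was lower (-1.30 ± 0.11), as were CXCL8 (-1.18 ± 0.27, with 1 saturated channel) and ESM1 (-0.96 ± 0.20). Calls were made for 972 of 15786 genes, 591 higher and 381 lower. Without the array of SAHA controls at 2 against 4 days 397 were called and without that of VPA controls 428. CXCL8 (-0.93 and -1.01) and ESM1 (-0.71 and -0.73) were called in neither case. Within 1 batch the time comparison can be made for 1 drug series at a time, and not for SAHA in DU-145. In PC3 the slope of the called genes on the values from all arrays was 1.03 for SAHA in batch A, and for VPA 1.07 in batch B and 1.01 in batch C. For VPA in DU-145 it was 1.05 in batch B. These arrays, too, are among those behind the comparisons.

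Lists called over time in DU-145 were mitosis, of which 2 of 45 were higher and 0 lower (6 and 0 adjusted over the list alone, median 0.067, adjusted p = 4.2e-07, and adjusted p = 0.21 with an estimated correlation), and heat shock genes, of which 2 of 23 were higher and 0 lower (6 and 0 adjusted over the list alone, median 0.082, adjusted p = 2e-05, and adjusted p = 0.17 with an estimated correlation). Of the genes of ribosome biogenesis 0 of 30 were higher and 2 lower (0 and 8 adjusted over the list alone, median -0.065, adjusted p = 2e-05, and adjusted p = 0.13 with an estimated correlation). Of the histone genes 0 of 25 were higher and 1 lower (0 and 2 adjusted over the list alone, median -0.068, adjusted p = 0.0021, and adjusted p = 0.13 with an estimated correlation). Of the DNA replication genes 0 of 39 were higher and 0 lower (0 and 7 adjusted over the list alone, median -0.041, adjusted p = 0.0035, and adjusted p = 0.13 with an estimated correlation). Of the antigen presentation genes 0 of 21 were higher and 0 lower (2 and 0 adjusted over the list alone, median 0.073, adjusted p = 0.0035, and adjusted p = 0.63 with an estimated correlation). In PC3 cytokines and NF-kappaB targets were called lower at 4 days, and 1 of 24 were higher and 7 lower (1 and 8 adjusted over the list alone, median -0.10, adjusted p = 4.6e-06, and adjusted p = 0.18 with an estimated correlation). For inhibitors of apoptosis 0 of 11 were higher and 3 lower (1 and 5 adjusted over the list alone, median -0.13, adjusted p = 0.00079, and adjusted p = 0.14 with an estimated correlation). For ribosome biogenesis genes 1 of 30 were higher and 5 lower (1 and 7 adjusted over the list alone, median -0.05, adjusted p = 0.00079, and adjusted p = 0.19 with an estimated correlation).

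Histone genes were called higher at 4 days in PC3, and 3 of 25 were higher and 0 lower (4 and 0 adjusted over the list alone, median 0.11, adjusted p = 0.00083, and adjusted p = 0.14 with an estimated correlation). For interferon-stimulated genes 5 of 24 were higher and 0 lower (5 and 0 adjusted over the list alone, median 0.027, adjusted p = 0.0089, and adjusted p = 0.31 with an estimated correlation). For actin-binding and tubulin genes in PC3 0 of 24 were higher and 3 lower (1 and 3 adjusted over the list alone, median -0.11, adjusted p = 0.0077, and adjusted p = 0.46 with an estimated correlation). For DNA replication genes 4 of 39 were higher and 0 lower (6 and 0 adjusted over the list alone, median 0.025, adjusted p = 0.032, and adjusted p = 0.18 with an estimated correlation). For the unfolded protein response 3 of 23 were higher and 7 lower (3 and 9 adjusted over the list alone, median -0.031, adjusted p = 0.033, and adjusted p = 0.35 with an estimated correlation). For mitosis genes 3 of 45 were higher and 0 lower (3 and 0 adjusted over the list alone, median 0.04, adjusted p = 0.048, and adjusted p = 0.52 with an estimated correlation).

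The change of each response between 2 and 4 days was taken from a fit with a parameter for each condition, whose residuals hold hybridisation error alone. It is signed, so a gene that responded more at 4 days may have risen more or fallen less. With SAHA in DU-145, MMP1 responded more at 4 days by 1.09 ± 0.12 (adjusted p = 0.0016), CDKN1A by 0.96 ± 0.092 and RGS2, a regulator of G-protein signalling, by 0.82 ± 0.096. The phosphatase subunit PPP1R35 (-0.61 ± 0.074), the zinc finger gene REPIN1 (-0.60 ± 0.10) and the dynein light chain DYNLT2B (-0.55 ± 0.081) had lower values at 4 days. The change was called for 327 of 15724 genes, 190 higher and 137 lower. Leaving out single arrays moved this count more than 1.5-fold for 16 of the 22, from 0 by limma (1123 at an unadjusted p under 0.05) without the array of DU-145 SAHA controls at 4 against 2 days to 818 without the 4-day direct array of SAHA in PC3. Without that array of controls none of the 6 genes was called, at 1.06, 1.02, 0.90, -0.53, -0.33 and -0.66, and all but REPIN1 were also lost without either direct array of SAHA in DU-145.

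With SAHA in PC3, CXCL8 responded more at 4 days by 1.68 ± 0.10 (adjusted p = 1.9e-05), the defensin DEFB103B (DEFB103) by 1.61 ± 0.080 and IL37 by 1.32 ± 0.088. ID1 (-1.79 ± 0.062), the carboxypeptidase PRCP (-1.36 ± 0.20) and S100A9 (-1.11 ± 0.17) had lower values at 4 days. The change was called for 355 of 15762 genes, 236 higher and 119 lower. Of the 22 arrays 8 moved the count more than 1.5-fold when left out, from 182 without the array of SAHA-treated PC3 cells at 4 against 2 days to 1122 without the 4-day direct array. S100A9 was not called without the array of SAHA controls (-0.64).

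With VPA in DU-145, the transcription factor EGR1 responded more at 4 days by 1.34 ± 0.090 (adjusted p = 4.3e-05), GKN1, a gastrokine, by 1.09 ± 0.095 and the membrane protein TMEM132A by 1.01 ± 0.21. ASNS, asparagine synthetase (-0.91 ± 0.095), PFDN6 (HKE2), a prefoldin (-0.66 ± 0.11), and the protease CTSZ (-0.58 ± 0.061) had lower values. The change was called for 339 of 15770 genes, 232 higher and 107 lower. Leaving out 12 of the 22 arrays moved the count more than 1.5-fold, from 7 without the 4-day direct array of VPA in DU-145 to 766 without the 4-day direct array of SAHA in PC3. TMEM132A (0.64), ASNS (-1.08), PFDN6 (-0.66) and CTSZ (-0.59) were not called without the array of VPA controls of DU-145, nor without either direct array of VPA in DU-145, where TMEM132A was 1.38, ASNS -0.72, PFDN6 -0.66 and CTSZ -0.58. TMEM132A was lost without any of 10 arrays.

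With VPA in PC3, CSTF2T, a cleavage stimulation factor, responded more at 4 days by 1.74 ± 0.085 (adjusted p = 5.1e-07), ACTG2, an actin of smooth muscle, by 1.28 ± 0.096 and IL37 by 1.19 ± 0.088. PFDN6 (-1.38 ± 0.11), ID1 (-1.32 ± 0.062) and S100A8, the partner of S100A9 (-1.23 ± 0.11), had lower values. The change was called for 538 of 15762 genes, 347 higher and 191 lower. Of the 22 arrays 7 moved the count more than 1.5-fold, from 109 without the array of VPA controls of PC3 to 1003 without the 4-day direct array of SAHA in PC3.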

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

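Chosen only after the results were seen were the tests of batch and of weak signal for the mitosis genes and the batch tests of the drug difference; the others were set out beforehand. The response to SAHA differed between PC3 and DU-145 in 1718 genes and that to VPA in 1672, by a test of the difference itself. The response also differed between 2 and 4 days, in 327 genes for SAHA in DU-145, 355 for SAHA in PC3, 339 for VPA in DU-145 and 538 for VPA in PC3.

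Mitosis genes fell more in DU-145 than in PC3 with both drugs. For VPA, a difference between hybridisation batches cannot give this, since all 4 direct arrays lie in batch B, where the median difference was 0.33. Weak signal is argued against by 0 of the 45 members lying near background in any channel. For SAHA the batch stays open, as 0 batches hold the response of both lines. A difference in how the lines slow their division is a candidate explanation that the design names and that was not tested further, and with an estimated correlation the VPA difference of this list was not called.

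Genes whose response differed between SAHA and VPA in DU-145 might have come from different controls of the 2 drug series. Called without the array that set VPA-treated against SAHA-treated cells at 2 days, 294 genes were checked on that array, and 99% had the same sign there, against 67.8% of all 15523 genes. That array holds both drugs on 1 slide of batch C, and its values had a slope of 0.839 ± 0.016 on the difference from the other arrays. The error is over genes of 1 array, which are not independent replicates. The size of the slope argues against a difference between hybridisation batches as the whole cause at 2 days. At 4 days such a difference stays open, since 0 batches hold SAHA- and VPA-treated DU-145 cells of that day. An effect of the drugs or of their doses could not be separated, as doses are not given. The left-out array holds single-source conditions that other arrays also hold, so a difference between single cultures stays open too.

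Changes of a response between 2 and 4 days could stem from dye bias left after the dye term, because the dyes of the direct arrays turn between the days. The dyes turn in opposite ways for the 2 drugs of a line, so such bias would give a correlation across genes below 0. The correlation was 0.266 in DU-145, the lower of the 2, and 0.425 in PC3, above all simulated values (at most 0.033 and 0.0397). A difference between the cultures of the 2 days, each a single source, and a change of the response with time both remain open. The pairs with equal dyes correlated at 0.0849 and 0.0262, also slightly above the simulated values (at most 0.0281 and 0.0237). Dye bias is therefore not excluded, and its share is not known.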

How the results depend on the processing

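Chosen after the data were seen were the alternatives for the gene lists other than the estimated correlation and the absent filter, and all those for the correlations of responses. Named genes kept their direction under every alternative run. For the treatments this was largely fixed in advance and is weak support. Each treatment change is the mean of its 2 direct arrays, so leaving out any other array does not move it where no spot is missing. The largest changes were also named for having the same sign at both days. With 1 array left out, 5259 of 5415 values stayed on their side of the threshold, 148 lost and 8 gained a call. Without a dye term 37 of 247 lost their call, without moderation 34, with the processed signals 30, and on the 8 direct arrays alone 21 of 161. The dye term for each batch cost 4 of 246, the arrays within a drug series 4 of 179, and the fit at the level of cultures, the value table and the absent background subtraction 3 each. The stricter filter, the absent filter, the mean of a name's probes and the fit with 16 conditions cost none. The cause of the changes in this part was not tested, except where fewer arrays or parameters are named.

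The fit with 16 conditions, which leaves day-to-day differences of a response out of the error, gave more genes: 2736 and 2629 for the line differences of SAHA and VPA, 1130 and 237 for the drug differences of DU-145 and PC3, and 869 and 2121 for time in DU-145 and PC3. The fit at the level of cultures gave 666 for the drug difference of DU-145 and 101 for its time comparison. On the 8 direct arrays alone, with fewer arrays for the spread, 1947, 841, 2343 and 949 genes were called for SAHA in DU-145 and PC3 and VPA in DU-145 and PC3, of which 571 rose and 270 fell for SAHA in PC3.

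Without a dye term the treatments gave 2845, 1679, 3163 and 1800 in the same order, the line differences 698 and 716, the drug differences 29 and 3, time 19 and 266, and the changes between 2 and 4 days 0, 31, 7 and 31 (SAHA in DU-145 and PC3, VPA in DU-145 and PC3), with 701 genes at an unadjusted p under 0.05 in limma for the first. A dye term for each batch gave 100 for time in DU-145, and 662 and 759 for the changes of SAHA in PC3 and VPA in DU-145. Tests without moderation gave 194 and 4 for the drug differences, 86 and 604 for time, and 76, 126, 169 and 321 for the changes between days.

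The processed signals gave 1095 for the line difference of SAHA, 35 (5 higher, 30 lower) and 2 (both higher) for the drug differences, 56 and 634 for time, and 27, 108, 44 and 255 for the changes between days. The correlation of responses was then 0.721 between drugs in PC3, and 0.486 and 0.498 between lines for SAHA and VPA. Without background subtraction the drug difference of PC3 held 16 genes (6 higher, 10 lower), and 4 among genes well above background in all 44 channels, where fewer were tested. List calls in the treatments were 49, and 8 with an estimated correlation. The other alternatives for the lists gave 48 to 52. With the processed signals the treatments had 12, 13, 13 and 10 called lists (11, 12, 12 and 14 otherwise, in the order of the treatments above), and of 60 calls in treatments and line differences 7 were lost. The drug differences then held 2 and 1 called lists in place of 3 and 3.

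With each array left out in turn, counts ran from 2564 to 4829 for SAHA in DU-145, 1601 to 3317 for SAHA in PC3, 2638 to 5213 for VPA in DU-145 and 1804 to 3591 for VPA in PC3. Line differences ran from 919 to 1807 (SAHA) and 751 to 1737 (VPA), and drug differences from 42 to 386 (DU-145) and 5 to 16 (PC3). The lines differed in 6720 to 7396 genes. Time gave 23 to 197 (DU-145) and 397 to 1036 (PC3), and the changes between days 0 (1123 unadjusted) to 818 and 182 to 1122 for SAHA in DU-145 and PC3, and 7 to 766 and 109 to 1003 for VPA. Correlations ran from 0.794 to 0.845 and 0.77 to 0.851 between drugs in DU-145 and PC3, and from 0.505 to 0.553 and 0.532 to 0.593 between lines for SAHA and VPA. Where a condition lost its lone direct array, its spread was assumed to be that of the others. Signal over background limits small changes: 10689 of 15787 genes were well above background in all 44 channels.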

Other observations

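Chosen after the results were seen was the count among splits with equal numbers of treated conditions. Other splits of the 8 conditions concerned into 4 and 4 were counted with the fit of 16 conditions. For PC3 against DU-145 control cells, 1 of 35 splits, the real one, gave as many genes (7829, and 6180 for the highest other). That is the smallest share that 35 splits can give, and many of the others still carry part of the line difference. The real split thus gave the most genes, but the splits cannot exclude chance. For 4 against 2 days, 22 of 35 splits gave as many genes in DU-145 (869, and 7022 for the highest other) and 14 of 35 in PC3 (2121, and 5763 for the highest other). Of these 35, 17 set unequal numbers of treated conditions against each other and so carry the treatment effect, which leaves that count without a bearing on time. The highest split in each line set treated against control conditions, and points to that structure of the samples. Among the 18 splits with equal numbers of treated conditions, 5 in DU-145 gave as many genes, the real one included, and 1 in PC3, the real one. The highest other gave 1281 genes in DU-145 and 1160 in PC3. In DU-145 the other splits with more genes than time (1281, 968, 1256 and 1130) each set both SAHA-treated against both VPA-treated conditions. That with 1130 genes is the drug difference itself. Such splits carry the drug difference and are no measure of chance for time, so that chance stays open there. In PC3 18 splits are too few for a share under 0.05.

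Among the genes called in a treatment, the change at 4 days against that at 2 days had a slope of 1.12 for SAHA in DU-145, 1.18 for SAHA in PC3, 1.17 for VPA in DU-145 and 1.09 for VPA in PC3. The change was larger at 4 days for 61.8%, 60.5%, 67% and 49.2% of them.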
